A study of Synechocystis sp. PCC 6803 with 4 samples.

How the data were processed

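The study measured transcripts of Synechocystis sp. PCC 6803 by RNA-seq on an Ion Torrent PGM instrument, from total RNA taken, per the labels' protocols, from the same cultures as a chromatin immunoprecipitation experiment. The 4 libraries were grouped by their treatment label into 2 starved-labelled libraries, kept 4 h without nitrogen, and 2 ammonium-labelled libraries. The authors deposited 1 file of raw read counts per library, and HTSeq 0.6.0 is named in the submitters' processing notes. The aligner, genome build, annotation and strand setting are not given in the sources used here. If reads that map to several places were discarded or shared between near-identical genes, the counts of such genes would be low or mixed, and without a stated strand setting antisense reads can be included. The deposited counts are whole numbers for 3228 identifiers, of which 50 have the identifier form of structural RNA (ribosomal, transfer and other stable RNAs) and 3178 do not. No row lacked a gene identifier. Rows of the ribosomal form held 10 to 91 counts per library, so the structural share comes from the other stable RNAs.

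The depth was 456103 to 1104406 counts per library, and 227693 to 632957 outside structural RNA. A count of 0 allows up to 3 counts, which on the TMM scale used for all CPM here is 3.23 and 2.48 CPM in the starved-labelled libraries and 8.26 and 3.19 CPM in the ammonium-labelled libraries; such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Between 65 and 139 of the 3178 other rows were at 0 in a library.

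Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on TMM-scaled libraries (factors 1.17 and 1.26 for the starved-labelled and 0.797 and 0.852 for the ammonium-labelled libraries), after the default filterByExpr filter (minimum count 10, minimum total 15), which left 2882 rows, 43 of them structural. The common biological coefficient of variation was 0.0993. Fold changes are starved-labelled minus ammonium-labelled on the log2 scale, the SE is the absolute log2 fold change divided by the square root of the F statistic, CPM values are scaled by TMM, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The design had no replicate block. Gene lists were tested with camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 18 lists, each with at least 3 tested members. Camera with a correlation estimated per list and fry were run beside it. Ranges of a list's adjusted p over its alternatives are of camera only, because fry tests a list against no change and not against other genes. None of the camera calls held with an estimated correlation, and with that setting camera uses only the residual degrees of freedom of the 4 libraries.

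The test, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where stated. The rule named 11 genes of nitrogen control in any case, the 10 largest changes each way among genes past the threshold with a mean count of at least 20 and CPM that did not overlap between groups, and up to 4 members of each list, by size of change among those past the threshold. It gave 89 genes. Gene symbols are the published designations of the locus tags, written down with the lists. They could not be matched to the reference gene table used here (assembly ASM28445v1), in which 0 of the 3228 identifiers were found, so each symbol is printed with its tag and no coordinates are given. A partial check by coding length was weak. For sll and slr tags it asked only for a minimum length, so it could pass wrong symbols, those of other ATP synthase subunits included. Of the 255 symbols, 99 occur once in that table. There, 97 of these have the coding length class that the prefix of the tag implies. atpH (ssl2615) and atpE (slr1330) did not and were dropped from the ATP synthase list, after their values had been seen; those letters name different subunits in different naming schemes. With both kept, an alternative chosen after seeing the data, the list had 9 tested members, 1 higher and 5 lower, a median of -0.51 and a camera adjusted p of 0.0117, or an adjusted p of 0.412 with an estimated correlation. Planned lists by product text (all ribosomal proteins, aminoacyl-tRNA ligases, transposases) were not formed, because no product text was used here. Of the 10 largest increases 9 had no symbol fixed beforehand, and of the 10 largest decreases 3 had none. These are printed by identifier only, without a function. Members not tested for low counts were petM, petN, cmpB, sigI, pstA2, isiB, exbB and exbD.

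The edgeR and camera steps were tested on simulated counts drawn from the means and library sizes of this comparison, over 2845 genes. Genes were drawn independently with the same dispersion, and far fewer were changed than were called in the data. At adjusted p under 0.05, 13 of 49 genes planted at 1.5-fold, 32 of 49 at 2-fold, 50 of 50 at 4-fold and 50 of 50 at 8-fold were recovered. In the simulation 4.27% of calls were false, a share that need not hold for the real libraries. The alternatives were RLE size factors, total counts without further scaling, no count filter, a mean count of at least 20, a replicate block, removal of structural RNA rows, leaving out each library in turn, DESeq2 1.42.0, limma-voom, the other gene list tests, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. Where a library is left out, its group has 1 library, which is assumed to vary like the other group.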

Results

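RNA from Synechocystis sp. PCC 6803, a unicellular freshwater cyanobacterium, was sequenced on an Ion Torrent instrument in 4 libraries. Per the labels, 2 libraries came from cells kept for 4 h without a nitrogen source after growth on ammonium, and 2 came from cells growing in an ammonium medium. The groups are called starved-labelled and ammonium-labelled throughout, because the transcripts of several nitrogen genes ran against those labels. Total counts were 792960 and 965493 in the starved-labelled libraries and 456103 and 1104406 in the ammonium-labelled libraries. A count of 3, the upper limit that a count of 0 allows, equalled 2.48 to 8.26 TMM-scaled CPM (the usual scaled read count) across the 4 libraries, for counting error only. Structural RNA rows, which are transfer RNAs and other stable RNAs by the form of their identifiers, took 35.2% ± 1.09 (SD, n = 2) of the counts in the starved-labelled group and 48.9% ± 1.73 (SD, n = 2) in the ammonium-labelled group. This share therefore moved with the groups, with an exact two-sided permutation p of 0.333, the smallest that 2 libraries against 2 allow. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.975 and 0.969 within the groups and 0.824 to 0.843 between them. The replicates of each group differed by more than sampling noise, with chi-square values per degree of freedom of 2.48 in the starved-labelled pair and 1.17 in the ammonium-labelled pair, and were counted as 2 samples each. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

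The comparison asks how transcript levels differ between cells in early acclimation to nitrogen starvation and cells supplied with ammonium, in a study of genes controlled by NtcA, the global nitrogen regulator of cyanobacteria. Transcripts for nitrogen uptake and assimilation were lower in the starved-labelled libraries, by up to 41.5-fold for glnA (slr1756), which encodes glutamine synthetase. Phycobilisome and photosystem I transcripts were also lower there, with list medians of -2.20 and -2.54 on the log2 scale. Ribosomal protein transcripts were higher there, with a list median of 1.19, as were gifA (ssl1911) and gifB (sll1515), which encode inhibitory proteins of glutamine synthetase. Textbook accounts of this organism put glnA, amt1 and urtA higher and gifA and gifB lower when nitrogen is short, so these directions are opposite to the group labels, whereas lower phycobilisome transcripts are the textbook direction for starvation.

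In the list of nitrogen uptake and assimilation genes, 17 of 22 members were lower in the starved-labelled libraries and 5 did not pass the test; adjusted over the list alone, 18 were lower and 1 was higher. glnA averaged 77.2 ± 5.17 CPM (SD, n = 2) in the starved-labelled libraries and 3200 ± 162 (SD, n = 2) in the ammonium-labelled libraries, a log2 fold change of -5.37 ± 0.14 (SE; edgeR adjusted p = 1.64e-22). The urea transporter genes urtA (slr0447) and urtB (slr1200) had log2 fold changes of -5.35 ± 0.13 and -5.11 ± 0.20, and the ammonium transporter gene amt1 (sll0108) one of -5.31 ± 0.13. The second glutamine synthetase gene, glnN (slr0288), was 24.5-fold lower, and glnB (ssl0707), which encodes the PII signal protein, was 14.2-fold lower. Among members outside the naming rule, chosen after their values were seen, the nitrate transporter gene nrtA (sll1450) had a log2 fold change of -3.42 and the isocitrate dehydrogenase gene icd (slr1289) one of -3.01. The list ranked low among all genes (camera adjusted p = 5.72e-12), and its adjusted p ran from 1.31e-27 to 0.282 over its alternatives, the highest being the p with an estimated correlation.

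ntcA (sll1423) itself had 293 ± 35.0 CPM (SD, n = 2) in the starved-labelled and 285 ± 32.9 in the ammonium-labelled libraries, a log2 fold change of 0.060 ± 0.14 that did not pass the test (adjusted p = 0.762). With scaling by total counts it was 0.61 with an adjusted p of 0.000697, beside a shift of the median of all genes to 0.57, and over its alternatives the adjusted p ran up to 0.919. Leaving out each library gave -0.11 to 0.21 for ntcA. gifA was 19.1-fold higher in the starved-labelled libraries, at 1545 ± 88.3 CPM (SD, n = 2) against 83.2 ± 10.8, and gifB was 5.09-fold higher. pirA (ssr0692), which encodes a small protein that binds PII, was 6.90-fold higher, and pirC (sll0944), which encodes another PII-interacting protein, was 16.5-fold lower. nblA1 (ssl0452), needed for phycobilisome degradation, had a log2 fold change of -0.28 ± 0.15 and did not pass (adjusted p = 0.131). Its value was 0.27 with total counts and -0.46 without starved-labelled replicate 1, where it passed with an adjusted p of 0.0213, and its adjusted p reached 0.587 over the alternatives. nblA2 (ssl0453) was lower at -0.71 ± 0.18 (adjusted p = 0.00153), with an adjusted p from 0.000357 to 0.425 over its alternatives, where total counts and DESeq2 ended the call. The sigma factor gene sigE (sll1689), a regulator of sugar catabolism, had -0.26 ± 0.21 (adjusted p = 0.336), and 0.29 with total counts.

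**Figure D1:**
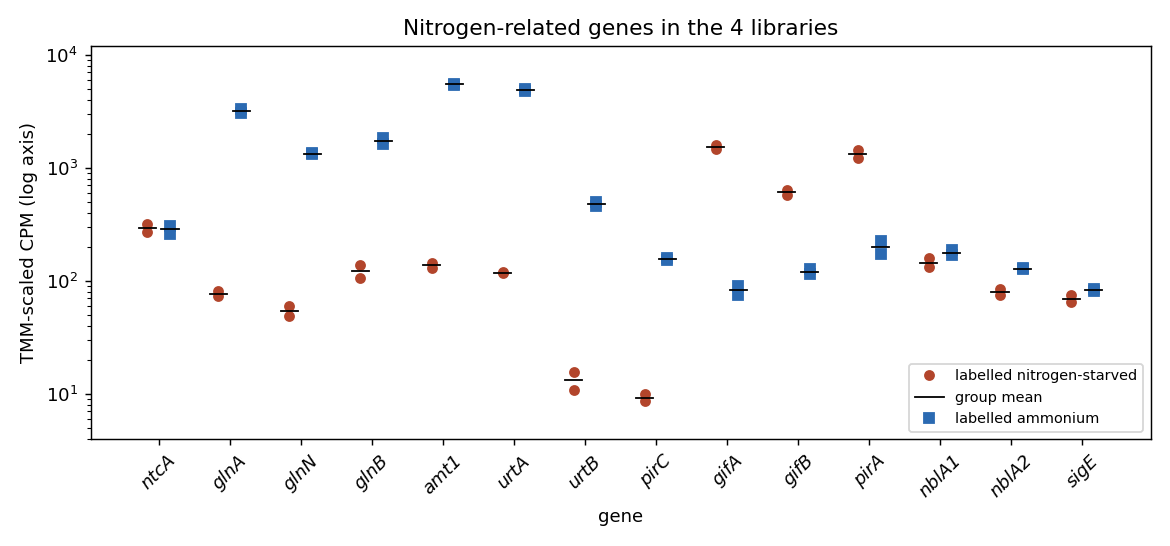
TMM-scaled CPM (log axis) of 14 nitrogen-related genes, with a point for each library, circles for starved-labelled and squares for ammonium-labelled libraries, and black bars for group means (n = 2). glnA lies at 77.2 CPM on average in the starved-labelled and 3200 in the ammonium-labelled libraries, gifA at 1545 and 83.2, and ntcA at 293 and 285.

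Light harvesting and photosystem I transcripts were lower as whole groups in the starved-labelled libraries. Of the phycobilisome structure list, 13 of 13 members were lower, and adjusted over the list alone also 13. cpcG2 (sll1471), which encodes a phycobilisome linker protein, had the largest change at -4.33 ± 0.26. The phycocyanin gene cpcA (sll1578) followed at -3.02 ± 0.11, and the allophycocyanin genes apcA (slr2067) at -2.93 and apcB (slr1986) at -2.82. Of the photosystem I list, 12 of 12 members were lower, and 12 adjusted over the list alone. psaF (sll0819) was 11.6-fold lower, psaD (slr0737) 11.4-fold, psaL (slr1655) 8.95-fold and psaM (smr0005) 8.59-fold. The camera adjusted p was 5.72e-12 for the phycobilisome list and 7.42e-12 for photosystem I; over their alternatives it ran from 6.25e-21 to 0.310 and from 2.44e-22 to 0.310, in each case highest as the p with an estimated correlation. The medians were -1.64 and -1.99 with total counts, and both groups moved alongside the structural RNA share of 35.2% against 48.9%.

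Photosystem II genes were divided, with 10 of 22 lower, 5 higher and 7 not past the test, and the same counts adjusted over the list alone. psbO (sll0427), which encodes the manganese-stabilising protein of the oxygen-evolving complex, was 4.19-fold lower, and psbT (smr0001) was 3.11-fold lower. psbA3 (sll1867) was 4.17-fold higher and psbD2 (slr0927) 2.41-fold higher; these genes have near-identical copies in the genome, so their counts are uncertain. The list did not pass (median -0.47, camera adjusted p = 0.0687), its median was 0.079 with total counts, and without starved-labelled replicate 1 it passed with an adjusted p of 0.0443, the lowest of its camera alternatives, which ran up to 0.505. Of 7 ATP synthase members, 4 were lower and 3 did not pass (6 lower adjusted over the list alone), with atpI (sll1322) at -1.33 ± 0.12, atpC (sll1327) at -1.18 and atpA (sll1326) at -0.91. atpG (sll1323) was at -0.51 and 0.036 with total counts, and leaving out starved-labelled replicate 2 or ammonium-labelled replicate 2 or using DESeq2 ended its call (adjusted p = 0.0565, 0.0506 and 0.149, in a range from 0.00137 to 0.853 over its alternatives). The ATP synthase list passed (median -0.51, camera adjusted p = 0.0108), but its median was 0.036 with total counts, which ended the call (adjusted p = 0.155), as did a mean count of at least 20 (adjusted p = 0.0531). Its adjusted p ran from 0.00631 to 0.320 over its alternatives, the highest being the p with an estimated correlation. In the list of the cytochrome b6f complex and soluble electron carriers, 3 of 9 tested members were lower, with ferredoxin petF (ssl0020) at -1.31, petD (slr0343) at -1.08 and petB (slr0342) at -0.90, and 6 did not pass, with the same counts adjusted over the list alone. Its median of -0.30 (camera adjusted p = 0.0575) was 0.25 with total counts (adjusted p = 0.321, the highest of its camera alternatives). The list passed without starved-labelled replicate 1 (adjusted p = 0.0322, the lowest), with a replicate block (adjusted p = 0.0373) and without structural RNA rows (adjusted p = 0.0377).

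Genes for pigments and for nitrogen storage were lower in part. Of 16 chlorophyll and bilin synthesis genes, 9 were lower, 3 higher and 4 did not pass; adjusted over the list alone 9 were lower and 4 higher. The heme oxygenase gene ho1 (sll1184) was 11.6-fold lower, chlB (slr0772) 7.89-fold lower and chlP (sll1091), which encodes geranylgeranyl reductase, 5.27-fold lower. chlL (slr0749) was uneven, with 10 and 78 counts in the starved-labelled libraries, and its log2 fold change of -1.78 became -3.68 without starved-labelled replicate 2, -1.20 without starved-labelled replicate 1 and -1.20 without ammonium-labelled replicate 2, where its adjusted p was 0.0831. Total counts and DESeq2 also ended the chlL call (adjusted p = 0.0591 and 0.230, in a range from 7.02e-24). The list passed (median -0.67, camera adjusted p = 0.0122), with an adjusted p from 0.000720 to 0.310 over its alternatives, the highest being the p with an estimated correlation, and its median was -0.12 with total counts. Of 11 arginine and cyanophycin genes, 6 were lower and 5 did not pass, with the same counts adjusted over the list alone. cphA (slr2002), which encodes the enzyme that makes the storage polymer cyanophycin, was 8.56-fold lower, argB (slr1898) was 2.98-fold lower and argG (slr0585) 2.39-fold lower. This list passed (median -0.55, camera adjusted p = 0.0108), with an adjusted p from 0.00671 to 0.310 over its alternatives, the highest being the p with an estimated correlation, and its median was -0.0018 with total counts.

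Ribosomal protein transcripts were higher almost throughout in the starved-labelled libraries, where 30 of 32 list members were higher and 2 did not pass, with 30 higher adjusted over the list alone. rplK (sll1743) averaged 1281 ± 104 CPM (SD, n = 2) against 334 ± 32.1 and had a log2 fold change of 1.92 ± 0.13. rpsC (sll1804) had 1.73 ± 0.13, rplP (sll1805) 1.71 ± 0.16 and rpsS (ssl3432) 1.54 ± 0.19. Those that did not pass were rpsL (sll1096), at -0.043 with an adjusted p of 0.817, and rpsB (sll1260), at 0.20 with an adjusted p of 0.166; both were named after their values were seen. rpsL passed at -0.27 without starved-labelled replicate 1 and at 0.50 with total counts (adjusted p = 0.0466 and 0.00161, in a range up to 0.940), and was 0.13 without starved-labelled replicate 2. rpsB passed as higher without starved-labelled replicate 2 and with total counts (adjusted p = 0.0395 and 1.12e-05, in a range up to 0.597). The list ranked high (camera adjusted p = 5.27e-14), with an adjusted p from 4.92e-19 to 0.310 over its alternatives, the highest being the p with an estimated correlation, and it moved alongside the lower structural RNA share of the same libraries.

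Among stress and regulatory genes, 6 of 10 chaperone genes were higher, 2 lower and 2 did not pass, with the same counts adjusted over the list alone. clpB1 (slr1641), which encodes a disaggregating ATPase, was 4.28-fold higher, the small heat shock protein gene hspA (sll1514) 2.44-fold, dnaK1 (sll0058) 1.97-fold and dnaK3 (sll1932) 1.96-fold; the list did not pass (median 0.55, camera adjusted p = 0.129), except with total counts (median 1.10, adjusted p = 0.00654, in a range up to 0.722 over its alternatives). Of 8 sigma factor genes tested, 3 were higher, 3 lower and 2 did not pass, also adjusted over the list alone. sigD (sll2012) was 4.68-fold higher and sigG (slr1545) 3.63-fold lower. sigA (slr0653) was higher at 0.55, a call that ended without ammonium-labelled replicate 2 (adjusted p = 0.145, in a range from 1.62e-07). sigF (slr1564) was lower at -0.59; its call ended without ammonium-labelled replicate 2 (log2 fold change -0.26, adjusted p = 0.610), without starved-labelled replicate 1 (adjusted p = 0.0532), with total counts (log2 fold change -0.039, adjusted p = 0.903) and with DESeq2 (adjusted p = 0.299), in a range from 0.0226 to 0.903. The sigma factor list had a median of -0.14 and a mean of 0.0077 (camera adjusted p = 0.980), and the median was 0.41 with total counts.

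Of 7 iron starvation genes tested, 5 were higher, 1 lower and 1 did not pass, also adjusted over the list alone. The iron transporter genes feoB (slr1392), futA1 (slr1295) and futA2 (slr0513) were 4.45-fold, 3.55-fold and 2.40-fold higher, whereas isiA (sll0247), which encodes a chlorophyll-binding protein made under iron shortage, was 2.49-fold lower. The list did not pass (median 1.16, 1.70 with total counts, camera adjusted p = 0.0575); it passed without ammonium-labelled replicate 1 and with total counts (adjusted p = 0.0317 and 0.0337, in a range from 0.0317 to 0.550 over its alternatives). Of 9 phosphate starvation genes tested, pstS1 (sll0680) was lower at -0.86 and pstA1 (sll0682) higher at 0.91, also adjusted over the list alone, and 7 did not pass. The pstA1 call ended without ammonium-labelled replicate 1 and with DESeq2 (adjusted p = 0.107 and 0.150, in a range from 0.00266 to 0.150), and its log2 fold change was 1.76 without ammonium-labelled replicate 2. The list had a median of -0.0090, 0.54 with total counts (camera adjusted p = 0.707).

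Carbon metabolism gave mixed lists that did not pass. Of 12 carbon fixation and carboxysome genes, 4 were higher, 2 lower and 6 did not pass, also adjusted over the list alone. The shell and scaffold genes ccmM (sll1031), ccmN (sll1032) and ccmL (sll1030) were at 1.39 ± 0.12, 1.12 ± 0.15 and 0.97 ± 0.16, and ccmK3 (slr1838) at -0.91, whose call ended when starved-labelled replicate 2, ammonium-labelled replicate 1 or ammonium-labelled replicate 2 was left out (adjusted p = 0.0561, 0.0690 and 0.121). Total counts and DESeq2 also ended the ccmK3 call (adjusted p = 0.337 and 0.199, in a range from 0.0107). The list's median was -0.046 and changed sign without starved-labelled replicate 2 or ammonium-labelled replicate 1 (0.0045 and 0.013); its mean was 0.18 and its camera direction up (adjusted p = 0.575), with a median of 0.51 under total counts. Of 15 inorganic carbon uptake genes tested, 6 were higher, 2 lower and 7 did not pass, also adjusted over the list alone. The bicarbonate transporter gene bicA (sll0834) was 3.12-fold higher, and ndhF3 (sll1732) and ndhD3 (sll1733), of a carbon dioxide uptake complex, 1.95-fold and 1.76-fold higher. cmpD (slr0044) was at 0.91, and its call ended without starved-labelled replicate 2, ammonium-labelled replicate 1 or ammonium-labelled replicate 2, where it was 0.56, 0.72 and 1.42 (adjusted p = 0.306, 0.170 and 0.0610, in a range from 0.00758 to 0.306). DESeq2 and limma-voom also ended the cmpD call (adjusted p = 0.275 and 0.0681). The uptake list had a median of 0.38, 0.92 with total counts (camera adjusted p = 0.236).

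Of 16 sugar catabolism and glycogen genes, 8 were lower, 2 higher and 6 did not pass; adjusted over the list alone 9 were lower and 3 higher. zwf (slr1843), which encodes glucose-6-phosphate dehydrogenase, was 3.67-fold lower, the glycogen synthesis gene glgC (slr1176) 2.52-fold and the glycogen phosphorylase gene glgP1 (sll1356) 2.48-fold lower, whereas the phosphofructokinase gene pfkA2 (sll0745) was 2.22-fold higher, a call that DESeq2 ended (adjusted p = 0.0803, in a range from 0.000439). The list did not pass (median -0.37, camera adjusted p = 0.0575); its median was 0.18 with total counts, and it passed without starved-labelled replicate 1, without ammonium-labelled replicate 2 and without structural RNA rows (adjusted p = 0.0322, 0.0496 and 0.0473, in a range from 0.0322 to 0.323 over its camera alternatives). Of 9 genes for polyhydroxybutyrate synthesis and the bidirectional hydrogenase, 2 were higher and 7 did not pass, with 1 higher adjusted over the list alone (median 0.082, 0.63 with total counts, camera adjusted p = 0.677). phaC (slr1830) at 0.83 and hoxH (sll1226) at 0.52 both lost their calls without ammonium-labelled replicate 2 (adjusted p = 0.141 and 0.339) and with DESeq2 (adjusted p = 0.140 and 0.324). hoxH also lost it without starved-labelled replicate 1 (log2 fold change 0.34, adjusted p = 0.261), without ammonium-labelled replicate 1 (adjusted p = 0.0615) and with the stricter count filter (adjusted p = 0.0537), and over the alternatives the adjusted p ran from 0.000319 to 0.141 for phaC and from 0.000673 to 0.339 for hoxH.

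Of 9 pilus genes, 4 were lower, 1 higher and 4 did not pass, also adjusted over the list alone. The major pilin gene pilA1 (sll1694) was 3.44-fold lower, at 9114 ± 316 CPM (SD, n = 2) in the starved-labelled libraries. pilT1 (slr0161), which encodes a retraction motor, was lower at 120 ± 4.52 CPM against 249 ± 61.1 (SD, n = 2) in the ammonium-labelled libraries. pilA2 (sll1695) was lower at -0.71, a call that ended with total counts (adjusted p = 0.210, in a range from 2.30e-12). pilN (slr1275) was higher at 0.71, and lost its call without starved-labelled replicate 1 or ammonium-labelled replicate 2 or with DESeq2 (adjusted p = 0.111, 0.122 and 0.154, in a range from 0.000302). The list had a median of -0.34, 0.21 with total counts (camera adjusted p = 0.165).

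**Figure D2:**
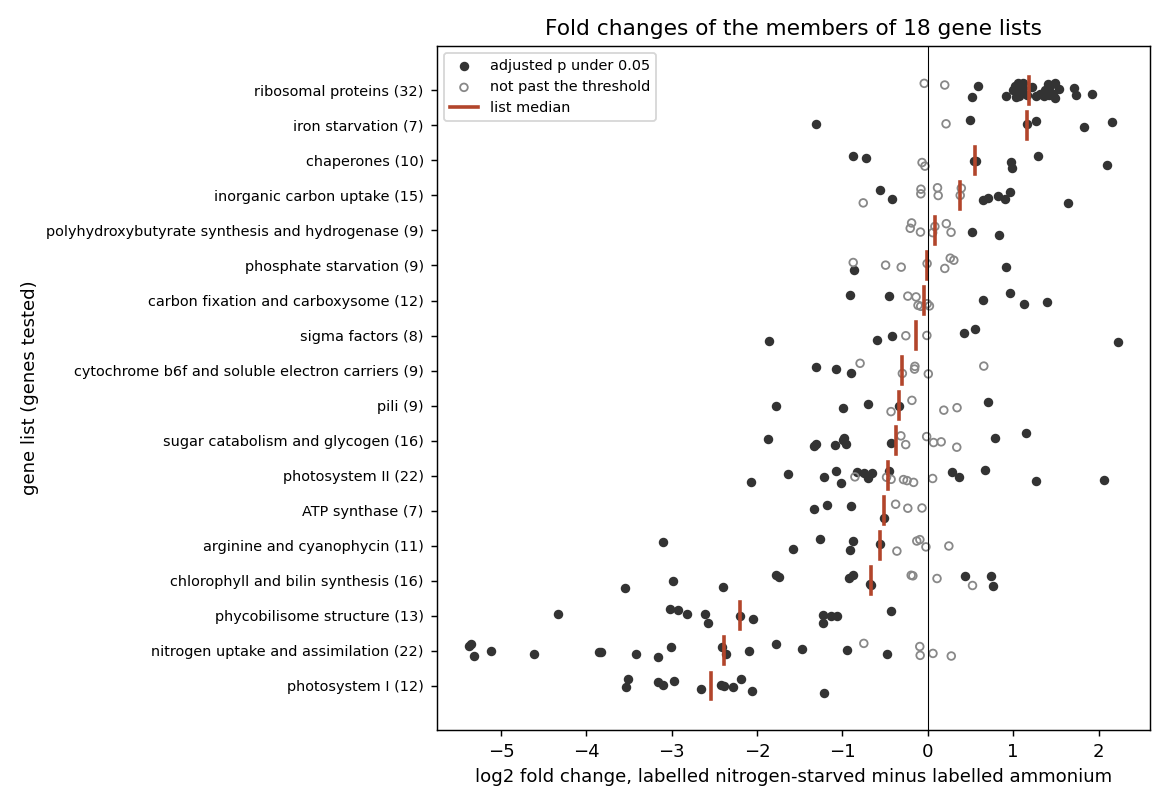
Log2 fold changes (starved-labelled minus ammonium-labelled) of the tested members of 18 gene lists, with the number tested in parentheses; filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. The photosystem I, nitrogen and phycobilisome lists lie lowest, with medians of -2.54, -2.38 and -2.20, and the ribosomal protein list highest, at 1.19; with total counts these were -1.99, -1.83, -1.64 and 1.74, and the medians of the photosystem II, ATP synthase, cytochrome b6f, carbon fixation, sugar, sigma factor, phosphate and pilus lists changed sign.

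Over all 2882 rows tested, 720 were higher and 638 lower in the starved-labelled libraries and 1524 were neither. At least 2-fold changes numbered 394 higher and 335 lower, and at least 8-fold changes 14 higher and 32 lower. The largest increases were those of sll1862 and sll1863, which carry no symbol here, at 5.24 ± 0.13 and 5.18 ± 0.15. Next among the increases without a symbol came ssl3044 (4.30), sll1566 (4.28), ssl2542 (4.12), slr1687 (3.65), sll0528 (3.58), slr1670 (3.52) and slr0895 (3.29). Decreases without a symbol were largest for sll1270 at -4.17 ± 0.15, ssl2384 at -4.11 ± 0.40 and ssr1375 at -3.90 ± 0.25. Some of these changes rest on few reads in the lower group. Counts in the starved-labelled libraries were 5 and 4 for ssl2384 and 7 and 23 for ssr1375. In the ammonium-labelled libraries they were 5 and 6 for slr0895 and 6 and 21 for ssl2542. CPM did not overlap between the groups in 2062 of the rows tested (71.5%), where chance gives 33.3%. Of 43 structural RNA rows tested, 35 were lower, with a median of -0.95 over the rows tested. With scaling by total counts instead of TMM the median log2 fold change of all rows moved from 0.021 to 0.57 and the split from 720 higher and 638 lower to 1322 and 290, so directions are relative to that shift. The strand setting of the counting is not given in the sources used here, so reads from antisense transcripts cannot be told apart from those of the named genes.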

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

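Keeping atpH and atpE in the ATP synthase list, described with the processing, was chosen after seeing the data, and the other settings before. The tally of named genes below also takes in genes from outside the naming rule. These are the 10 light and oxidative stress genes of the next section, and nrtA, icd, rpsL and rpsB, named after their values were seen. Across the alternatives, named genes kept sign and side of the threshold in 1175 fits, lost a call in 47, gained one in 7 and changed sign in 10, of which 2 (atpG and ocp) are among the lost and 1 (rpsL) among the gained calls; list medians under camera kept both in 166, lost a call in 9, gained one in 10 and changed sign in 15, 1 of these (ATP synthase) among the lost calls, and fry gained 4. With total counts the sign changed for atpG (sll1323) to 0.036, nblA1 to 0.27, sigE to 0.29, gpx1 to 0.48, ocp to 0.19 and rpsL to 0.50, and for the list medians of photosystem II to 0.079, ATP synthase to 0.036, cytochrome b6f to 0.25, carbon fixation to 0.51, sugar to 0.18, sigma factors to 0.41, phosphate to 0.54 and pili to 0.21. The phosphate median was also 0.23 at a mean count of at least 20 and 0.00082 with the replicate block. Leaving out each library gave -0.11 to 0.21 for ntcA, -0.27 to 0.13 for rpsL and -0.40 to 0.16 for gpx1, and medians of -0.078 to 0.013 for carbon fixation, -0.38 to 0.067 for sigma factors, -0.54 to 0.041 for phosphate and -0.035 to 0.32 for polyhydroxybutyrate and hydrogenase. With total counts 1322 rows were higher and 290 lower, against 720 and 638; 1011 of these calls were shared with the TMM fit, 1010 in the same direction, and the median of all rows moved to 0.57, which follows from dropping the TMM factors. DESeq2 called 406 higher and 390 lower, 796 of 796 shared; the cause of the lower number was not tested. A minimum absolute log2 fold change of 1 left 394 higher and 335 lower, by construction. The gene list test called 7 lists, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 11 with fry, which asks another question. With a replicate block 786 rows were higher and 681 lower, 1356 of the 1467 calls shared; deviations of same-numbered libraries correlated at 0.19 across genes, and the numbers are not stated to pair the samples. Leaving out each library gave 520 to 708 rows higher, 466 to 678 lower and 7 to 10 lists called. At this depth and with 2 libraries per group, 26.5% of simulated 1.5-fold changes were recovered; the simulation did not vary depth.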

Other observations

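The tests of label exchange, of a single wrong label and of scaling given here were chosen after the results were seen, and the test of the light and oxidative stress list before the values of its genes were seen. A further 10 genes tied to high light and oxidative stress, a list chosen after the table of all genes was seen but before the values of these genes were looked at, were mostly higher in the starved-labelled libraries: 7 were higher, 1 lower and 2 did not pass the edgeR test. Of the high-light-inducible protein genes, the list held only hliB (ssr2595), hliC (ssl1633) and hliD (ssr1789). They had log2 fold changes of 2.21 ± 0.22, 1.97 ± 0.18 and 1.12 ± 0.37 (SE, n = 2 per group). The protease genes ftsH2 (slr0228) and ftsH3 (slr1604), of the complex that removes damaged photosystem II protein, had 2.04 ± 0.11 and 1.83 ± 0.11, and the peroxidase gene gpx2 (slr1992) and the superoxide dismutase gene sodB (slr1516) had 0.63 and 0.43. Without ammonium-labelled replicate 2 the calls of hliD (0.46, adjusted p = 0.460) and gpx2 (adjusted p = 0.0954) ended, as they did with DESeq2 (adjusted p = 0.204 and 0.0611), and without ammonium-labelled replicate 1 that of sodB ended (adjusted p = 0.0704); over the alternatives the adjusted p started from 0.00268, 1.01e-05 and 3.88e-07. ocp (slr1963), which encodes the orange carotenoid protein, was lower at -0.36, but 0.19 with total counts. Its call ended there (adjusted p = 0.0581) and without starved-labelled replicate 2 (log2 fold change -0.22, adjusted p = 0.0555), ammonium-labelled replicate 1 (adjusted p = 0.124) or ammonium-labelled replicate 2 (adjusted p = 0.114), in a range from 1.02e-07, and it was -0.56 without starved-labelled replicate 1. Of all 2882 rows tested, 720 were higher. These symbols, too, could not be matched to the reference gene table.

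Nitrogen assimilation genes were lower in the libraries labelled nitrogen-starved, the opposite of the textbook response. A single wrong label is argued against, because the lowest correlation of log2 CPM within a group (0.969) exceeded the highest between groups (0.843) by 0.127. Scaling, with or without structural RNA rows, is argued against as the whole cause of the list median of -2.38. Rescaling shifts all genes nearly alike, and under total counts the median of all rows moved only from 0.021 to 0.57. The list median was therefore bound to stay low. It was at most -1.83 under RLE, total counts and removal of structural rows. An exchange of the labels of all 4 libraries is a possible explanation that cannot be told apart from the labels as given. It would turn glnA, amt1, gifA, pirA, pirC, icd, zwf, glgP1, nblA2 (-0.71) and the ribosomal protein list to the textbook direction. Of these, glnA, amt1 and gifA raised the question, so their turning is no separate support for an exchange. The phycobilisome list, at -2.20, would turn away from the textbook direction. nblA2 fell short of the mark set for it in this test, and with total counts it was at -0.16 and not called. An exchange would also make the photosystem I list, at -2.54, higher under starvation, and phaC (0.83) and pfkA2 (1.15) lower. These were not part of the test. In the main fit nblA1 at -0.28, ntcA at 0.060 and sigE at -0.26 did not pass, so they favour neither labelling. With total counts ntcA passed as higher at 0.61, beside a shift of the median of all rows to 0.57. A response to nitrogen removal as labelled stays open, untested.

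Photosystem I and phycobilisome transcripts were lower and ribosomal protein transcripts higher in the same libraries. Scaling, with or without structural RNA rows, is argued against as the whole cause. The photosystem I median was at most -1.99 and the ribosomal protein median at least 1.18 under the other scalings. Rescaling shifts all genes nearly alike and by less than these medians, so that outcome was largely fixed in advance. A light or oxidative stress response in the starved-labelled libraries is a candidate explanation. In that list 7 of the 10 genes were higher, past the mark of 6 in the test. The count cannot separate such a response from one to the nitrogen supply, since both would fall on the same libraries. The list was also chosen after the table of all genes was seen. Its hli genes share a family and its ftsH genes a complex, so the count of 7 is not of independent genes. Over the alternatives with all 4 libraries the number ran from 5 with DESeq2, which falls under the mark, to 8 with total counts. The labels name no difference in light, and the nitrogen supply, or an exchange of labels, stays open for this pattern as well.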
